A study of Mus musculus with 12 samples.

How the data were processed

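The samples are mRNA from the cerebral cortex of single mouse embryos, microdissected, flash frozen and extracted with TRIzol, with libraries made by a stranded mRNA kit (TruSeq Stranded mRNA). There are 12 libraries in 4 groups of 3 embryos. No label says whether embryos of different groups with the same replicate number are matched, and the main fit did not pair them. After group means were removed, WT and HARE5Hs/Hs libraries of replicates 1, 2 and 3 correlated at 0.0963, 0.336 and 0.124 at E12.5. At E14.5 these values were −0.112, −0.144 and −0.443. Per the submitters' processing notes, reads were aligned with STAR to mm39 and compared with DESeq2; versions, the counting tool, the strand setting and the design formula are not given in the sources used here. Per the file headers, each of the 2 deposited tables holds, for 24411 genes, the authors' expected count and FPKM per library and the authors' log2 fold change, its standard error, p-value and adjusted p-value for E14.5 against E12.5 in 1 genotype. The deposited expected counts are whole numbers. Counts and FPKM of the 12 libraries are the same in both tables (0 cells differ, with a tolerance of 1e-09 for FPKM). Each table also holds 12 columns for 6 libraries that match no sample of the series, and these were not used here. Litter and sex of the embryos are not labelled.

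The comparisons, the main settings, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The authors' expected counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with groups and a minimum count of 10 (14311 genes), libraries were scaled by TMM, and all 12 libraries entered a quasi-likelihood fit with 1 mean per group and no block. The 6 contrasts were E14.5 against E12.5 in WT and in HARE5Hs/Hs, HARE5Hs/Hs against WT at E12.5, at E14.5 and averaged over both ages, and the genotype by age interaction. P-values are 2-sided and adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05, and a fold of 2 counts as doubled or halved. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F, an approximation. Log2 CPM used a prior count of 2. Where a group holds 3 counts or fewer in sum, ratios are given with a 95% counting interval or as a lower bound. The interval treats the counts summed over the 3 embryos as independent and leaves out the spread between embryos, so it is too narrow.

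Named genes are the 10 with the largest fold in each direction among genes that passed, had a mean CPM of at least 2, a named symbol and no overlap of libraries between groups, up to 4 members of each list with the smallest p in each contrast, and Fzd8. Some genes that meet this rule are not reported here. Where fewer than 10 genes passed, the 5 with the smallest p are given as not passing. Ttr, Col1a1, Xist, Adamts19, Gm14308 and Gm14430, and the genes named only as DESeq2 calls, were named after their values were seen, as were Ckap2, Esco2, Ptprk and Wnt8b.

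The 30 gene lists, drawn up from general knowledge, are radial glia, intermediate progenitors, neurons, deep layer neurons, upper layer neurons, Cajal-Retzius cells, synapse and ion channels, axon guidance, Wnt pathway components, Wnt target genes, Notch pathway, S phase, G2 and M phase, early temporal progenitor genes, gliogenic genes, forebrain patterning, genes around Fzd8, p53 target genes, hypoxia, immediate early genes, ventral telencephalon, cortical hem and choroid plexus, diencephalon, meninges and mesenchyme, surface epithelium, endothelial cells and pericytes, microglia and macrophages, erythroid cells, ribosomal proteins and replication-dependent histones. A list of mitochondrially encoded genes has no member in the tables and was not used here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM, adjusted over 30 lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, and its preset correlation does not carry the spread between embryos in full. The list of genes around Fzd8 includes Fzd8 itself and Pard3, which lies on another chromosome in the reference used (GRCm38, with 95% of symbols matched); only gene order was taken from that reference, as the authors used mm39.

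The age axis projects each library's log2 CPM on the age difference averaged over genotypes, over the 8132 genes past the threshold for it, scaled so that the mean of E12.5 libraries is 0 and of E14.5 libraries 1. Groups were compared by an exact permutation of 3 against 3.

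Alternatives were the DESeq2 Wald test, DESeq2 size factors in edgeR, no filter, a stricter filter (CPM of at least 1 in at least 3 libraries), only the libraries compared, the replicate number as a block, log2 CPM of Xist as a covariate, leaving out each library of the compared groups in turn, and for lists an estimated correlation and fry. A pseudocount alternative did not apply because counts were held. Gene-length offsets recovered from count over FPKM, limma voom with sample quality weights, and leaving E14.5 HARE5Hs/Hs replicate 3 out of contrasts that do not compare it were chosen after seeing the data. Simulated counts with planted changes gave the shares of false and recovered calls for edgeR and DESeq2. They come from a single draw per planted group, with gene means over all 12 libraries and edgeR's dispersions. Each draw held 50 planted genes at each log2 fold of 0.5, 1, 2 and 3. Genes were drawn independently, so the counts lack differences that genes of an embryo share, and they may favour edgeR. On the same kind of counts, the age axis returned 0.165 for a planted shift of 0.2 and −0.00119 for 0 (14073 genes), and camera called the shifted list and 1 other (14139 genes). Reads, alignments and coordinates were not analysed here.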

Results

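RNA sequencing of the cerebral cortex covers 12 single mouse embryos in 4 groups of 3: WT and HARE5Hs/Hs at E12.5, and WT and HARE5Hs/Hs at E14.5. HARE5 is an enhancer of Fzd8, which encodes a Wnt receptor, and its sequence changed fast on the human lineage. HARE5Hs/Hs embryos carry the human version. At E12.5 most cortical progenitors still divide to make progenitors and early deep-layer neurons, and by E14.5 neurogenesis is near its peak. Total expected counts ran from 11593202 in E14.5 HARE5Hs/Hs replicate 3 to 17670103 in E12.5 HARE5Hs/Hs replicate 2. Of 24411 genes in the deposited tables, 6454 had no count in the 12 libraries and 14311 passed the filter on low counts. Changes are log2 fold changes with their standard error (SE), and levels are CPM (counts scaled to library size) as mean ± SD over n = 3 embryos. The words "edgeR adjusted p" stand for edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14311 genes. "Rose" and "fell" are kept for genes with edgeR adjusted p under 0.05. Each p-value rests on 3 embryos per group, litter is not labelled, and stage within the day and dissection are part of the spread between embryos.

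Genes that mark neighbouring tissue and embryo sex varied between embryos within every group. Ttr, a gene of the choroid plexus, ran from 14.3 to 196 CPM at E12.5. At E14.5 it stood at 16.3, 138 and 482 CPM in WT replicates 1, 2 and 3 and at 373, 635 and 0.364 CPM in HARE5Hs/Hs. Col1a1, a collagen gene of the meninges, stood at 57.4, 13.8 and 132 CPM in E14.5 WT and at 59.7, 20 and 1.55 CPM in E14.5 HARE5Hs/Hs. Xist, expressed from the inactive X of females, was at 1340 CPM or more in 8 libraries. It was at 0.798 CPM or less in E12.5 WT replicate 1, E12.5 HARE5Hs/Hs replicate 3, E14.5 WT replicate 2 and E14.5 HARE5Hs/Hs replicate 3, so each group holds 2 females and 1 male. Hemoglobin genes took 0.443% to 0.632% of counts at E12.5 except in HARE5Hs/Hs replicate 3 (1.51%). They took 0.0753% to 0.224% in E14.5 WT and 0.256% to 0.565% in E14.5 HARE5Hs/Hs. On the first principal component of log2 CPM (60.4% of variance) E12.5 libraries lay between −65.4 and −30.4 and E14.5 libraries between 19.3 and 98.2. The highest of these, E14.5 HARE5Hs/Hs replicate 3, also lay lowest on the second component (−56.1; 9.98% of variance), held the fewest detected genes (14537) and had the least Ttr and Col1a1. Within groups the spread of counts exceeded counting noise, with a chi-square per degree of freedom of 12.3 to 26.9.

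Fzd8, the gene HARE5 acts on, was expressed at a similar level in both genotypes. At E12.5 it stood at 58.1 ± 12.3 CPM in WT and 61.7 ± 17.7 CPM in HARE5Hs/Hs, and at E14.5 at 52.9 ± 2.44 and 53.6 ± 3.41 CPM (SD, n = 3). The genotype difference was 0.09 at E12.5 (SE 0.18, edgeR adjusted p = 1), 0.02 at E14.5 (SE 0.18, edgeR adjusted p = 0.975) and 0.05 over both ages (SE 0.13, edgeR adjusted p = 0.914). The age change differed between genotypes by −0.07 (SE 0.25, edgeR adjusted p = 0.979). Between ages Fzd8 did not pass in WT (−0.14, SE 0.18, edgeR adjusted p = 0.583) or in HARE5Hs/Hs (−0.20, SE 0.18, edgeR adjusted p = 0.376). The E12.5 difference hangs on single embryos: without HARE5Hs/Hs replicate 1, which held 82.1 CPM against 51.2 and 51.7 CPM in replicates 2 and 3, it was −0.18. In counts simulated with changes planted in E12.5 HARE5Hs/Hs (14122 genes), edgeR recovered 24% of genes planted at 0.5 and 60% at 1. There 50 genes were planted at each size at once, and edgeR made 140 calls, which eases the adjusted threshold. The real contrast had 0 calls, so a lone change would be recovered less often than these shares. With 3 embryos per group, a small change of a gene such as Fzd8 would thus mostly go uncalled, and a doubling could go uncalled too.

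The genes that share the Fzd8 region showed no passing genotype difference either. Of 16 measured genes on the list around Fzd8, which counts Fzd8 itself and Pard3 of another chromosome, 0 passed at E12.5 (median 0.08, camera adjusted p = 0.455) and 0 at E14.5 (median 0.04, camera adjusted p = 0.925, although the mean was −0.10), both over all genes and adjusted over the list alone. In gene order along the reference chromosome, Wac is the next tested protein-coding gene, and Ccny and Mpp7 lie 2 away. Mpp7, a scaffold gene of cell junctions, stood at 23.1 ± 5.38 CPM in WT and 15.8 ± 1.72 CPM in HARE5Hs/Hs at E14.5 and did not pass (−0.54, SE 0.18, edgeR adjusted p = 0.342). Between ages Epc1, a chromatin gene of this list, rose in WT (0.49, SE 0.10, edgeR adjusted p = 0.00236) and in HARE5Hs/Hs (0.55, SE 0.10, edgeR adjusted p = 0.000732). Bambi, a decoy receptor of the TGF-beta family, fell by 1.49 (SE 0.24, edgeR adjusted p = 0.00077) and 1.10 (SE 0.24, edgeR adjusted p = 0.00279).

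**Figure D1:**
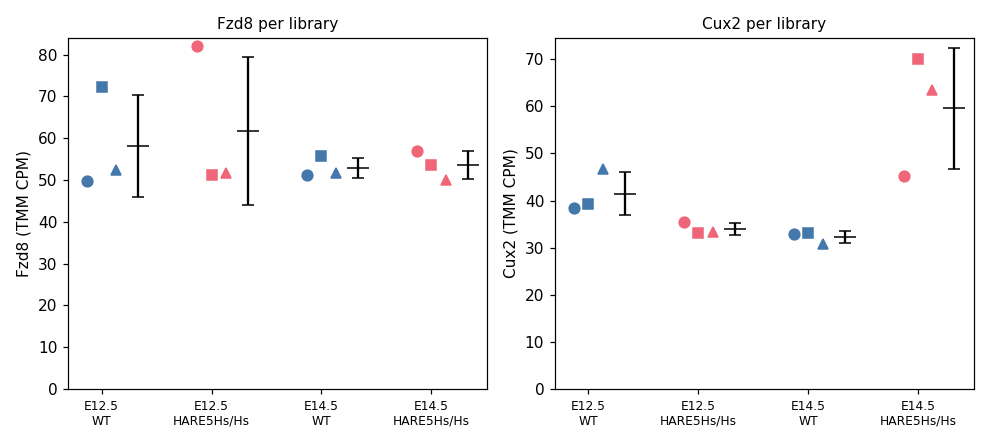
CPM of Fzd8 and Cux2 in each library; circle, square and triangle are replicates 1, 2 and 3, bars give mean ± SD (n = 3), blue WT, pink HARE5Hs/Hs. Fzd8 overlaps between genotypes at both ages, while Cux2 at E14.5 lies at 30.8 to 33.1 CPM in WT and 45.3 to 70.1 CPM in HARE5Hs/Hs.

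In WT cortex, 12 of 14 measured neuron genes and 18 of 19 synapse and ion channel genes rose between E12.5 and E14.5. Both lists were called (camera adjusted p = 1.34e-06 and 9.26e-08), but not with an estimated correlation (camera adjusted p = 0.412 each). Neurod6, a transcription factor of young excitatory neurons, rose by 4.25 (SE 0.56, edgeR adjusted p = 0.000299), from 28.7 ± 12.48 to 544 ± 80.6 CPM (SD, n = 3). Sox5, which directs subcortical projection neurons, rose from 62.8 ± 7.81 to 295 ± 56.5 CPM (2.23, SE 0.20, edgeR adjusted p = 5.19e-05). Eomes, the transcription factor of intermediate progenitors, rose from 135 ± 15.5 to 389 ± 41.9 CPM (1.53, SE 0.16, edgeR adjusted p = 0.000115). Unc5d, a guidance receptor of multipolar upper-layer cells, rose by 3.92 (SE 0.49, edgeR adjusted p = 0.000223). The adhesion gene Cntn2 rose by 2.54 (SE 0.25, edgeR adjusted p = 6.68e-05). The glutamate receptor gene Gria1 rose by 4.53 (SE 0.60, edgeR adjusted p = 0.000288). The potassium channel gene Kcnq3 rose by 3.97 (SE 0.48, edgeR adjusted p = 0.000187). Reln, secreted by Cajal-Retzius cells, rose from 97.7 ± 19.3 to 489 ± 32.4 CPM (2.32, SE 0.26, edgeR adjusted p = 0.000146). Lhx5 of the same cells fell by 1.84 (SE 0.35, edgeR adjusted p = 0.00186). Among the largest folds, the brain proteoglycan gene Bcan rose by 5.66 (SE 0.60, edgeR adjusted p = 0.00011). Tiam2, an activator of Rac, rose from 8.06 ± 7.06 to 295 ± 62.0 CPM (5.20, SE 0.59, edgeR adjusted p = 0.000153). Nos1, of nitric oxide synthesis, rose from 1.83 ± 0.712 to 51.6 ± 16.0 CPM (4.82, SE 0.46, edgeR adjusted p = 6.16e-05). Drd1, a dopamine receptor gene, held 1 count over the 3 E12.5 embryos and 206 over the 3 at E14.5, a ratio of 225 (95% counting interval 40 to 8940). This and the later counting intervals leave out the spread between embryos. Gpr176, Ifi203, Mc4r, Htra1, Grm5 and March4 complete the 10 largest rises.

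Many genes of early progenitors, the cell cycle and non-neural cells fell over the same interval. All 10 early temporal progenitor genes and all 18 S phase genes fell. Of G2 and M phase genes 8 of 16 fell, of meninges and mesenchyme 5 of 12, and of microglia and macrophages 3 of 12. With an estimated correlation 0 of the 30 lists passed. Hmga2, which holds progenitors in an early state, fell by 3.83 (SE 0.33, edgeR adjusted p = 4.05e-05), from 513 ± 211 to 36.2 ± 6.44 CPM. Lin28b, a let-7 inhibitor, fell by 2.50 (SE 0.36, edgeR adjusted p = 0.000478). The cyclin gene Ccnd1, a Wnt target, fell from 388 ± 102 to 77.1 ± 15.7 CPM (−2.33, SE 0.21, edgeR adjusted p = 5.19e-05). The replication gene Mcm2 fell by 0.59 (SE 0.10, edgeR adjusted p = 0.00122) and the mitotic kinase gene Plk1 by 0.59 (SE 0.11, edgeR adjusted p = 0.00224). The Notch effector Hes5 fell by 0.92 (SE 0.15, edgeR adjusted p = 0.000719) and the Wnt receptor gene Fzd7 by 1.12 (SE 0.14, edgeR adjusted p = 0.000223). Hbb-bh1, an embryonic globin gene, fell from 456 ± 207 to 3.75 ± 2.01 CPM (−6.92, SE 0.61, edgeR adjusted p = 4.46e-05). Shox2, a gene of the diencephalon, held 281 counts at E12.5 and 0 at E14.5, at least 85.7-fold lower. Olig3, a patterning gene, held 317 and 1, a ratio of 290 (95% counting interval 51.7 to 11500). Fezf1 fell by 6.35 (SE 1.24, edgeR adjusted p = 0.00233), from 20.5 ± 5.86 to 0.244 ± 0.365 CPM. Hemgn, Pkhd1l1, Adra2b, Acp5 and Tfap2b are also among the 10 largest falls. Not all progenitor genes fell: Fabp7 of radial glia rose by 0.98 (SE 0.14, edgeR adjusted p = 0.000466). Nfib and Nfix, which drive progenitor maturation, rose by 2.21 (SE 0.31, edgeR adjusted p = 0.00038) and 2.45 (SE 0.38, edgeR adjusted p = 0.000622). In all 2863 genes rose and 2178 fell, 916 of them at least doubled and 828 at least halved. The share that rose, 56.8%, rests on the scaling of libraries and was 52.5% with DESeq2 size factors. The count of 5041 depends on single embryos, with 3245 without E14.5 WT replicate 1, 3794 without E12.5 WT replicate 2, and 3866 without E14.5 WT replicate 2.

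The same course ran in HARE5Hs/Hs cortex, and 5 of the 10 largest rises and 5 of the 10 largest falls were of the same genes as in WT. Sox5 rose from 70.3 ± 14.7 to 414 ± 101 CPM (2.56, SE 0.20, edgeR adjusted p = 1.27e-05). Eomes rose from 150 ± 41.1 to 418 ± 15.0 CPM (1.48, SE 0.16, edgeR adjusted p = 6.34e-05). Grm5, a metabotropic glutamate receptor gene, rose by 6.62 (SE 0.79, edgeR adjusted p = 9.23e-05). Nos1 rose from 1.76 ± 1.45 to 77.9 ± 15.5 CPM (5.48, SE 0.46, edgeR adjusted p = 1.87e-05). Abcc8, a subunit gene of an ATP-sensitive potassium channel, rose from 1.16 ± 0.209 to 39.8 ± 11.2 CPM (5.10, SE 0.29, edgeR adjusted p = 2.62e-06). Tiam2 rose from 13.9 ± 9.56 to 440 ± 88.7 CPM (4.99, SE 0.58, edgeR adjusted p = 7.81e-05). Drd1 held 0 counts at E12.5 and 225 at E14.5, at least 87.2-fold higher. Bcan, Vsnl1, Thy1, Kcnh3 and Dync1i1 complete the 10 largest rises. Vsnl1 at E14.5 (13.7 ± 20.1 CPM) had an SD above its mean. Hmga2 fell from 482 ± 166 to 30.0 ± 5.41 CPM (−4.0, SE 0.33, edgeR adjusted p = 1.86e-05). Ccnd1 fell from 409 ± 96.1 to 79.7 ± 5.61 CPM (−2.36, SE 0.21, edgeR adjusted p = 2.41e-05). Lef1, a nuclear effector of Wnt, fell by 1.00 (SE 0.20, edgeR adjusted p = 0.00182) and the S-phase gene Rrm2 by 0.88 (SE 0.11, edgeR adjusted p = 0.000118). Fgf17, a signal of the rostral patterning centre, fell from 29.6 ± 4.86 to 0.782 ± 0.236 CPM (−5.26, SE 0.81, edgeR adjusted p = 0.000357). Hbb-bh1 fell from 621 ± 346 to 12.2 ± 3.68 CPM (−5.67, SE 0.55, edgeR adjusted p = 3.61e-05). Acp5, of osteoclasts and macrophages, held 521 counts and then 3, a ratio of 149 (95% counting interval 50.8 to 726). Pkhd1l1, Alox12, Treml2, Hemgn, Adra2b, Six2 and Hsd11b2 complete the 10 largest falls. In all 3385 genes rose and 3153 fell, with 1193 at least doubled and 1131 at least halved. Without E12.5 HARE5Hs/Hs replicate 2 the count was 4930 in place of 6538. The heat-shock gene Hspa1b passed (4.42, SE 1.505, edgeR adjusted p = 0.0304) but stood at −0.81 without E14.5 HARE5Hs/Hs replicate 3, so its call is that of 1 embryo.

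The 2 genotypes shared most age changes. Of the genes called, 2501 rose in both and 1801 fell in both, against 677 and 480 if the calls were independent. Fold changes of all 14311 tested genes correlated at r = 0.844 across genes. Over the 7274 genes called in either, the first principal component of the 2 sets of fold changes had a slope of 1.12 (HARE5Hs/Hs over WT). This is not a regression slope. The genes were picked by these same calls, of which HARE5Hs/Hs had more, so it does not measure a larger age change in HARE5Hs/Hs. The age comparisons in the deposited DESeq2 results hold 5232 changes in WT and 6598 in HARE5Hs/Hs, of which 4728 and 6230 were also called here in the same direction (r = 0.987 and 0.989 across genes). There, Fzd8 stands at −0.16 in WT (SE 0.22, DESeq2 adjusted p = 0.622) and −0.20 in HARE5Hs/Hs (SE 0.22, DESeq2 adjusted p = 0.482).

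Lists of neuronal genes moved up with age as groups and lists of cycling and non-neural genes moved down. Camera called 17 lists in each genotype, with adjusted p = 0.412 to 0.478 in WT and 0.438 to 0.578 in HARE5Hs/Hs with an estimated correlation. That way 0 of 30 passed, while fry called 17 and 21. Of 14 measured neuron genes 12 rose in WT and 14 in HARE5Hs/Hs (medians 1.42 and 1.57, camera adjusted p = 1.34e-06 and 6.91e-07). Of 19 synapse and ion channel genes 18 and 19 rose (2.03 and 2.33, camera adjusted p = 9.26e-08 and 1.01e-08), and of 13 intermediate progenitor genes 9 and 8 (0.97 and 0.76, camera adjusted p = 0.000298 and 0.00143). Of 12 deep-layer genes 8 and 9 rose (1.19 and 1.28, camera adjusted p = 0.00357 and 0.00111), and of 11 upper-layer genes 7 and 9 (1.43 and 1.25, camera adjusted p = 0.00357 and 0.000525). Of 20 axon guidance genes 13 rose in each genotype (1.09 and 0.99, camera adjusted p = 0.00171 and 0.00214). All 18 S phase genes fell in both genotypes (−0.55 and −0.81, camera adjusted p = 1.14e-07 and 6.08e-09). So did all 10 early temporal progenitor genes (−1.58 and −1.70, camera adjusted p = 1.77e-07 and 2.12e-06). Of 16 G2 and M phase genes 8 and 15 fell (−0.27 and −0.59, camera adjusted p = 0.00258 and 2.12e-06). Of 14 Wnt target genes 5 and 9 fell (−0.48 and −0.89, camera adjusted p = 0.0267 and 0.00798). Meninges and mesenchyme stood lower (5 and 9 of 12 fell, camera adjusted p = 0.00536 and 0.00103), as did endothelial cells and pericytes (8 and 10 of 13, camera adjusted p = 0.00357 and 0.00384). Microglia and macrophages (3 and 5 of 12, camera adjusted p = 0.0267 and 0.0101) and diencephalon (5 and 4 of 7, camera adjusted p = 0.00181 and 0.0343) stood lower. Hypoxia (5 and 7 of 12, camera adjusted p = 0.0321 and 0.0173) and ribosomal proteins (23 and 54 of 77, camera adjusted p = 1.77e-07 and 1.37e-09) also stood lower. Erythroid cells stood lower in WT (6 of 9 fell, camera adjusted p = 0.000657) with 5 of 9 falling in HARE5Hs/Hs (camera adjusted p = 0.0587). Cortical hem and choroid plexus stood lower in HARE5Hs/Hs (6 of 12 fell, camera adjusted p = 0.0346) with 5 of 12 falling in WT (camera adjusted p = 0.0834). Against their lists, 1 deep-layer gene fell in WT, 1 upper-layer gene in each genotype, and 3 and 2 axon guidance genes, while 1 hypoxia gene rose in each genotype and 1 endothelial gene in WT.

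Most other lists moved in both directions within themselves, while all 3 measured genes of the surface epithelium stood lower in each genotype. Radial glia had 4 genes up and 4 down of 18 in WT and 4 up and 8 down in HARE5Hs/Hs (camera adjusted p = 0.911 and 0.337). Its median, mean and direction of test differed in sign in both genotypes. Wnt pathway components had 4 up and 12 down of 33 in WT and 6 up and 15 down in HARE5Hs/Hs (camera adjusted p = 0.126 and 0.21). The Notch pathway had 1 up with 4 down of 16 and 1 up with 5 down (camera adjusted p = 0.0665 and 0.0843). Cajal-Retzius cells had 1 up and 3 down of 9 in each genotype (camera adjusted p = 0.291 and 0.176). Gliogenic genes had 3 up and 2 down of 13, then 4 up and 3 down (camera adjusted p = 0.593 and 0.652), and forebrain patterning had 3 up and 8 down of 14, then 4 up and 7 down (camera adjusted p = 0.0904 and 0.176). Counts for genes around Fzd8 were 1 up and 2 down of 16 in each genotype (camera adjusted p = 0.972 and 0.724). For p53 target genes they were 1 up and 2 down of 12, then 2 up and 3 down (camera adjusted p = 0.735 and 0.675), and for immediate early genes 1 up and 1 down of 10, then 2 up and 2 down (camera adjusted p = 0.39 and 0.724). Ventral telencephalon had 1 up and 3 down of 15, then 1 up and 5 down (camera adjusted p = 0.243 and 0.652). Surface epithelium had 2 down of 3, then 1 (camera adjusted p = 0.0904 and 0.21), and replication-dependent histones 3 up of 12, then 2 up and 1 down (camera adjusted p = 0.911 and 0.816). Gliogenic genes and histones in WT, and histones in HARE5Hs/Hs, likewise differed in sign between median, mean and test. Adjusted over the list alone, the counts changed in WT for radial glia (5 down), upper layer neurons (8 up, 2 down), Wnt pathway components (13 down), Wnt target genes (7 down), genes around Fzd8 and p53 target genes (1 down each), hypoxia (7 down), microglia and macrophages (2 down) and ribosomal proteins (20 down). In HARE5Hs/Hs, adjusted over the list alone, they changed for radial glia (5 up, 9 down), intermediate progenitors (9 up, 1 down), upper layer neurons (10 up), axon guidance (14 up, 3 down), Wnt pathway components (7 up), G2 and M phase (16 down), endothelial cells and pericytes (11 down) and ribosomal proteins (57 down). Every other list kept its count.

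**Figure D2:**
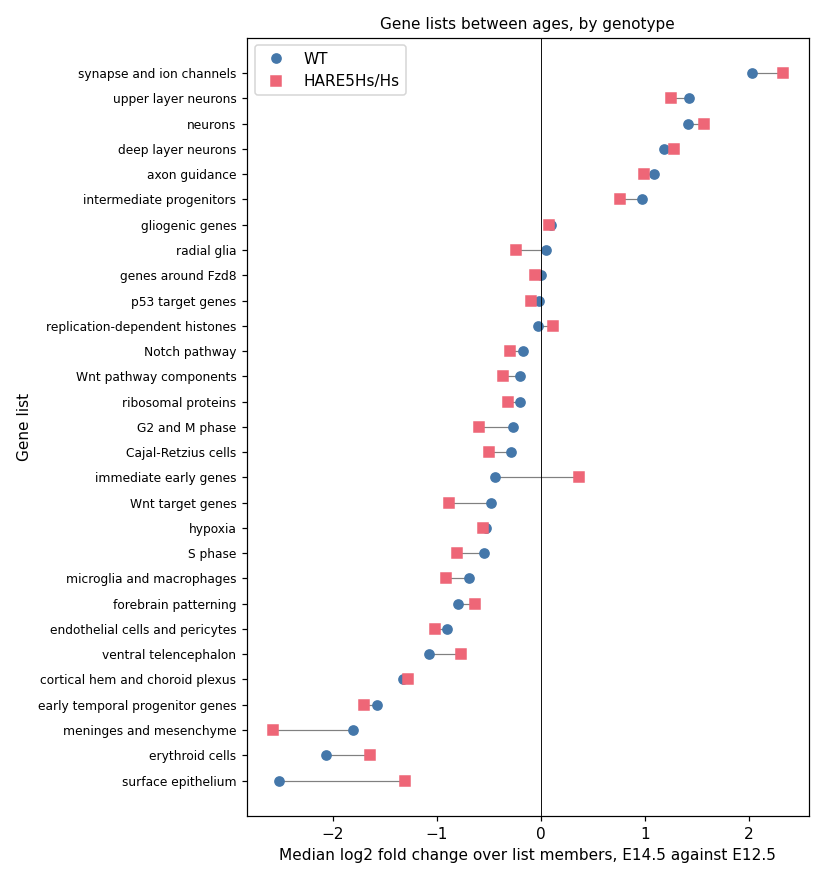
Median log2 fold change, E14.5 against E12.5, over the measured members of 29 gene lists; circles WT, squares HARE5Hs/Hs. Synapse and ion channel genes lie at 2.03 and 2.33 and early temporal progenitor genes at −1.58 and −1.70; the diencephalon list is left out because 5 of its 7 members are near 0 counts in a group.

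At E12.5 no gene passed between genotypes, and 3 of the 5 genes with the smallest p-values differed by less than 0.5. Chrm1, a muscarinic receptor gene, stood at 0.227 ± 0.1 CPM in WT and 1.01 ± 0.412 CPM in HARE5Hs/Hs (2.12, SE 0.52). Scamp4, a vesicle trafficking gene, stood at 56.1 ± 2.28 and 44.8 ± 3.24 CPM (−0.32, SE 0.08) and Mrpl32, of the mitochondrial ribosome, at 13.9 ± 0.614 and 19.4 ± 1.26 CPM (0.48, SE 0.12). Pex6 of the peroxisome (−0.32, SE 0.09) and the unnamed gene 5730508B09Rik (1.05, SE 0.30) complete the 5 smallest p-values, each with edgeR adjusted p = 1. Neurod6 stood at 59.8 ± 45.9 CPM in HARE5Hs/Hs against 28.7 ± 12.48 CPM in WT (1.06, SE 0.51, edgeR adjusted p = 1). Wnt7b, a Wnt ligand gene of cortical progenitors, stood at 141 ± 20.4 against 178 ± 24.6 CPM (−0.34, SE 0.14, edgeR adjusted p = 1). edgeR called 0 of 14311 genes, with 322 at unadjusted p under 0.05 (196 higher, 126 lower). With no differences a share of about 0.05 of genes would be expected there, and 322 is below that share. DESeq2 called 0 and limma voom 0. The count of 322 became 696 without HARE5Hs/Hs replicate 2, 511 without WT replicate 2 and 510 without WT replicate 1.

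Neuronal genes leaned up and Wnt pathway genes leaned down in HARE5Hs/Hs at E12.5. Camera called 5 lists, with adjusted p = 0.586 for Wnt pathway components and 0.829 for the other 4 with an estimated correlation, and fry called 0. Of 14 neuron genes 13 stood above 0 (median 0.33, camera adjusted p = 0.0273), of 19 synapse and ion channel genes 18 (0.27, camera adjusted p = 0.0273) and of 9 erythroid genes all 9 (0.68, camera adjusted p = 0.0195). Of 33 Wnt pathway components 25 stood below 0 (−0.16, camera adjusted p = 0.0195), among them the receptor genes Fzd7 (−0.29, SE 0.14, edgeR adjusted p = 1) and Fzd1 (−0.24, SE 0.11, edgeR adjusted p = 1). Of 16 Notch pathway genes 15 stood below 0 (−0.10, camera adjusted p = 0.0273). Ventral telencephalon genes, of another neuronal lineage, were not called but lay further up than the neuron lists (13 of 15 above 0, median 0.98, camera adjusted p = 0.224; adjusted p = 0.861 with an estimated correlation). No member of any of the 30 lists passed over all genes or adjusted over the list alone. Without HARE5Hs/Hs replicate 1, which lies latest of the E12.5 libraries on the first principal component (−30.4), the neuron and synapse lists turned over (camera adjusted p = 0.643 each). The erythroid list was lost without HARE5Hs/Hs replicate 3, with 1.51% hemoglobin (camera adjusted p = 0.795), and also without WT replicate 1 or 2, and the Notch list without any of 4 embryos. Wnt pathway components had camera adjusted p = 0.0605 without WT replicate 1 and 0.0611 without HARE5Hs/Hs replicate 1, and were just past 0.05 without WT replicate 2. Other fits gained calls, with 10 lists without HARE5Hs/Hs replicate 2, 8 without replicate 3 and 6 without WT replicate 1. Gliogenic genes, endothelial cells and pericytes, and ribosomal proteins, none of them called with all libraries, differed in sign between median, mean and test.

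At E14.5 no gene passed between genotypes, and the 5 smallest p-values belong to Cux2, Ptprt, Cdca5, Syn3 and Fam19a1. Cux2, a transcription factor of upper-layer neurons and their progenitors, stood at 32.3 ± 1.27 CPM in WT and 59.6 ± 12.8 CPM in HARE5Hs/Hs (SD, n = 3; 0.88, SE 0.14, edgeR adjusted p = 0.342). Ptprt, a synaptic phosphatase gene, stood at 11.7 ± 2.58 and 31.8 ± 9.23 CPM (1.44, SE 0.27), and Syn3, a synapsin gene, at 29.5 ± 2.45 and 48.8 ± 6.23 CPM (0.73, SE 0.14). Cdca5, needed for sister chromatid cohesion, stood at 45.9 ± 5.12 and 32.1 ± 3.32 CPM (−0.51, SE 0.10) and the secreted-factor gene Fam19a1 at 0.134 ± 0.133 and 2.64 ± 1.17 CPM (4.23, SE 0.84), all 4 with edgeR adjusted p = 0.342. The deep-layer gene Ldb2 (0.94, SE 0.24) and the sodium channel gene Scn3a (0.72, SE 0.18) also stood higher, each with edgeR adjusted p = 0.342. Tnfrsf19, a Wnt target of progenitors (299 ± 29.7 and 177 ± 58.0 CPM; −0.76, SE 0.18), Lef1 (−0.64, SE 0.20), Cdk1 (−0.35, SE 0.10) and Ccnb1 (−0.34, SE 0.09) stood lower, each with edgeR adjusted p = 0.342. edgeR called 0 of 14311 genes, with 1708 at unadjusted p under 0.05 (852 higher, 856 lower). This is above the share of 0.05 expected with no differences, though another split of the same libraries gave 1712. By comparison limma voom called 0 and DESeq2 35 (25 higher, 10 lower). The DESeq2 calls include Cux2 (0.91, SE 0.16, DESeq2 adjusted p = 6.16e-05), Ptprt (1.46, DESeq2 adjusted p = 0.000488), Syn3, Lhx6, Calb1, Scn3a, Cdca5 and Tnfrsf19. They also include Gm14308 and Gm14430, near-identical copies between which reads may have been split. In counts simulated with changes planted in E14.5 HARE5Hs/Hs, 14.8% of DESeq2 calls were false against 4.11% for edgeR. There edgeR recovered 32%, 60% and 90% of genes planted at 0.5, 1 and 2 (14143 genes). Many changes were planted at once, which eases the adjusted threshold. The simulated counts also used edgeR's own dispersions and lack differences that genes of an embryo share, so the rates need not hold for the real calls. The edgeR count hangs on HARE5Hs/Hs replicate 1, with 19 calls without it, among them Cux2 (1.07, edgeR adjusted p = 0.0083), Adamts19 (−1.87, edgeR adjusted p = 0.0083) and Tnfrsf19 (−1.03, edgeR adjusted p = 0.0183). The count of 1708 became 876 without HARE5Hs/Hs replicate 3, 920 without replicate 2, 2835 without replicate 1 and 1070 without WT replicate 3.

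As groups, neuronal and erythroid genes stood higher than the other genes at E14.5 and cell-cycle genes lower. Camera called 12 lists, with adjusted p = 0.584 to 0.631 with an estimated correlation, and fry called only immediate early genes (fry adjusted p = 0.0348). All 14 neuron genes (median 0.43, camera adjusted p = 0.000225) and all 19 synapse and ion channel genes (0.71, camera adjusted p = 2.18e-05) lay above 0. Upper layer neurons (0.46, camera adjusted p = 0.00123) and deep layer neurons (0.20, camera adjusted p = 0.0299) stood higher too. All 18 S phase genes (−0.25, camera adjusted p = 3.67e-07) and all 16 G2 and M phase genes (−0.25, camera adjusted p = 3.67e-07) lay below 0. Wnt target genes (−0.32, camera adjusted p = 0.00648) and ribosomal proteins (−0.10, camera adjusted p = 1.4e-05) also stood lower. Groups from outside the cortical lineage moved too. Ventral telencephalon genes such as Lhx6 of migrating interneurons (11.1 ± 3.65 and 30.0 ± 10.2 CPM; 1.43, SE 0.33, edgeR adjusted p = 0.342) stood higher (1.49, camera adjusted p = 0.0243). Meninges and mesenchyme stood lower (−1.11, camera adjusted p = 0.00397) and erythroid genes higher (1.62, camera adjusted p = 3.67e-07). Hba-a1, an alpha-globin gene, stood at 737 ± 412 CPM in WT and 2407 ± 1080 CPM in HARE5Hs/Hs (1.71, SE 0.53, edgeR adjusted p = 0.342), and Alas2, of heme synthesis, at 17.1 ± 9.39 and 53 ± 26 CPM (1.62, SE 0.53, edgeR adjusted p = 0.342). Globin genes share near-identical reads, so the split among them is uncertain. Immediate early genes stood higher (0.47, camera adjusted p = 0.0165), with Hspa1b at 27.5 ± 46.3 CPM in HARE5Hs/Hs, a value carried by replicate 3. Over all genes 0 members passed. Adjusted over the list alone 9 erythroid, 4 synapse and ion channel, 3 immediate early, 2 upper-layer, 1 deep-layer and 1 ventral telencephalon gene were higher and 6 G2 and M phase genes and 1 Wnt target gene lower. The deep-layer and meninges calls were lost without WT replicate 3 (camera adjusted p = 0.105 and 0.114) and without HARE5Hs/Hs replicate 3 (0.204 and 0.237). Wnt target genes were lost without WT replicate 3 (camera adjusted p = 0.0649) and immediate early genes without WT replicate 1 (just past 0.05). Ventral telencephalon was lost without WT replicate 1 (camera adjusted p = 0.106) and HARE5Hs/Hs replicate 2 (camera adjusted p = 0.21). Intermediate progenitors, gliogenic genes, forebrain patterning, genes around Fzd8, surface epithelium and histones, none of them called, differed in sign between median, mean and test.

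**Figure D3:**
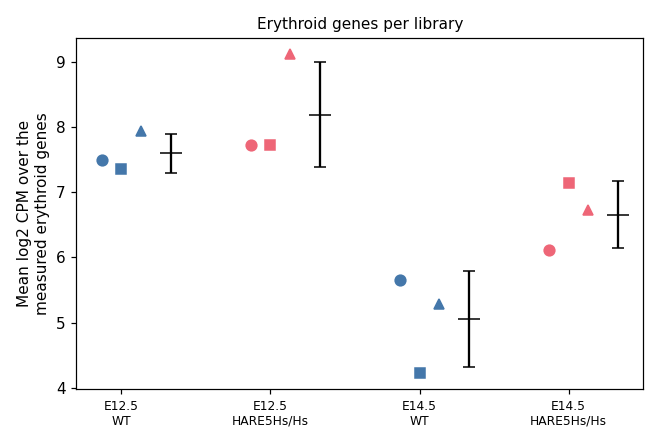
Mean log2 CPM over the measured erythroid genes in each library, with mean ± SD per group (n = 3). The E14.5 HARE5Hs/Hs libraries lie at 6.11, 7.14 and 6.72 and the E14.5 WT libraries at 5.65, 4.23 and 5.29; E12.5 HARE5Hs/Hs replicate 3 (9.12) lies above all others.

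The age change itself differed between genotypes for no gene by edgeR. Cux2 came nearest: it stood lower at E14.5 than at E12.5 in WT (41.4 ± 4.61 and 32.3 ± 1.27 CPM) and higher in HARE5Hs/Hs (34.0 ± 1.31 and 59.6 ± 12.8 CPM), a difference of 1.17 (SE 0.20, edgeR adjusted p = 0.921). Pno1, of ribosome assembly (−0.72, SE 0.16), Hyal3 (4.43, SE 1.02), Atrnl1 (0.53, SE 0.12) and the fatty-acid elongase gene Elovl5 (−0.45, SE 0.11) follow, each with edgeR adjusted p = 0.921. Wnt7b (0.67, SE 0.20) leaned in opposite directions at the 2 ages, with edgeR adjusted p = 0.921. edgeR called 0 genes, with 731 at unadjusted p under 0.05 (334 higher, 397 lower), about the share of 0.05 expected with no differences. By limma voom 0 passed, and DESeq2 called only Cux2 (DESeq2 adjusted p = 0.00159). Without E14.5 HARE5Hs/Hs replicate 1 edgeR called Cux2 (1.35, edgeR adjusted p = 0.0184) and Adamts19 (−2.04, edgeR adjusted p = 0.044). The count of 731 became 1387 without E14.5 HARE5Hs/Hs replicate 1, 1139 without E12.5 HARE5Hs/Hs replicate 1 and 459 without E14.5 HARE5Hs/Hs replicate 2.

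S phase genes (median −0.25, camera adjusted p = 3.42e-05), G2 and M phase genes (−0.32, camera adjusted p = 8.7e-07), ribosomal proteins (−0.10, camera adjusted p = 0.000615) and meninges and mesenchyme (−0.90, camera adjusted p = 0.0301) stood lower in this difference. These and the 2 lists that stood higher had adjusted p = 0.945 with an estimated correlation, and fry called 0. Erythroid cells (0.79, camera adjusted p = 0.0034) and diencephalon (3.58, camera adjusted p = 0.0301) stood higher, though the diencephalon median is 0.27 without its 5 members near 0 counts. The 6 calls became 3 without E12.5 WT replicate 3 or E12.5 HARE5Hs/Hs replicate 2 and 13 without E14.5 HARE5Hs/Hs replicate 1. Only the S phase and the G2 and M phase calls held in every fit that leaves out 1 embryo, and ribosomal proteins turned over without E12.5 WT replicate 1. Over all genes 0 members passed. Adjusted over the list alone 1 upper-layer gene was higher and 2 G2 and M phase genes lower. Axon guidance, Wnt pathway components, the Notch pathway, gliogenic genes, p53 target genes and histones, none of them called, differed in sign between median, mean and test.

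Averaged over both ages, no gene passed between genotypes. Chrm1 (1.68, SE 0.33) and Calb1, a calcium buffer gene (1.55, SE 0.33), stood higher, each with edgeR adjusted p = 0.508. Cdca5 (−0.33, SE 0.07), the antiviral adaptor gene Mavs (−0.38, SE 0.08) and Rbms2 (−0.27, SE 0.06) stood lower, each with edgeR adjusted p = 0.508. edgeR called 0 genes, with 1366 at unadjusted p under 0.05 (764 higher, 602 lower), and 0 passed by DESeq2 or limma voom. The 1366 are above the share of 0.05 expected with no differences. However, 14 of 100 relabellings of genotype within age, the real one among them, gave as many. The count of 1366 became 2248 without E14.5 HARE5Hs/Hs replicate 1, 788 without replicate 3 of that group and 716 without E12.5 HARE5Hs/Hs replicate 1. Camera called 18 of 30 lists, with adjusted p = 0.364 to 0.743 with an estimated correlation, and fry called 0. Leaving out 1 embryo at a time left 10 to 18 calls (10 without E12.5 WT replicate 3). Of the 18, neurons (median 0.38), synapse and ion channels (0.56), upper layer neurons (0.34), deep layer neurons (0.14), axon guidance (0.17), immediate early genes (0.28), ventral telencephalon (1.41) and erythroid cells (1.15) stood higher, with camera adjusted p from 1.03e-07 to 0.0458. Wnt pathway components (−0.08), Wnt target genes (−0.33), the Notch pathway (−0.14), S phase (−0.15), G2 and M phase (−0.11), hypoxia (−0.18), Cajal-Retzius cells (−0.34), cortical hem and choroid plexus (−0.28), meninges and mesenchyme (−0.57) and ribosomal proteins (−0.05) stood lower, with camera adjusted p from 3.18e-05 to 0.0494. The calls for deep layer neurons, axon guidance, ventral telencephalon, the Notch pathway, hypoxia, Cajal-Retzius cells, cortical hem and choroid plexus, meninges and mesenchyme and ribosomal proteins were each lost without at least 1 embryo. Cortical hem and choroid plexus turned over without E14.5 HARE5Hs/Hs replicate 3. Over all genes 0 members passed. Adjusted over the list alone 9 erythroid, 3 upper-layer, 3 synapse and ion channel and 1 immediate early gene were higher and 1 forebrain patterning gene lower. Radial glia, gliogenic genes, forebrain patterning and genes around Fzd8, none of them called, differed in sign between median, mean and test.

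Placed on an axis of the age change, where WT and HARE5Hs/Hs together average 0 at E12.5 and 1 at E14.5 over 8132 age-changing genes, E14.5 HARE5Hs/Hs embryos lay later on average than WT, with overlap. At E14.5 the scores were 0.908, 1.09 and 1.29 in HARE5Hs/Hs (1.10 ± 0.192) and 0.967, 1.01 and 0.737 in WT (0.904 ± 0.146), a difference of 0.191 (exact 2-sided permutation p = 0.3; the smallest possible with 3 against 3 is 0.1). At E12.5 they were 0.219, −0.108 and −0.0142 in HARE5Hs/Hs and 0.0121, −0.0972 and −0.0108 in WT, a difference of 0.064 (exact 2-sided permutation p = 0.9). The neuronal and cell-cycle lists lie along this axis, so their genotype differences and the scores are not separate findings. The E14.5 difference ran from 0.085 without WT replicate 3 to 0.307 without HARE5Hs/Hs replicate 1.

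**Figure D4:**
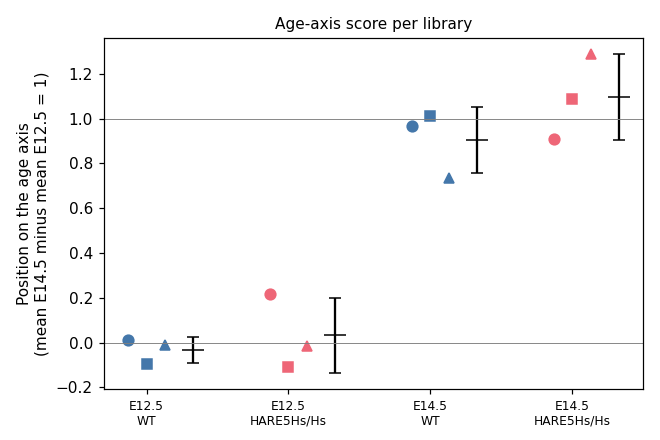
Score on the age axis for each library, with mean ± SD per group (n = 3) and lines at 0 and 1. E14.5 HARE5Hs/Hs replicate 3 (1.29) lies latest and E14.5 WT replicate 3 (0.737) earliest of the E14.5 embryos.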

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

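The tests on erythroid genes and both tests that leave out E14.5 HARE5Hs/Hs replicate 3 were chosen only after the result was seen. The splits of the libraries were set beforehand. Gene-length offsets were chosen after seeing the data, and the bounds for the gene-length and neighbouring-tissue tests were written before their own values were seen. The conditions that offsets must move the age calls and that a bound be passed by more than the SE were added after those values were seen.

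Groups of genes that shifted between genotypes were set against other splits of the same libraries. Between ages, 1 of 10 splits (the real one) gave as many genes in WT (5041, highest other 0) and 1 of 10 in HARE5Hs/Hs (6538, highest other 0), and as many lists came from 1 of 10 in WT (17, highest other 12) and 3 of 10 in HARE5Hs/Hs (17, highest other 19). Between genotypes at E12.5, 10 of 10 splits gave as many genes at unadjusted p under 0.05 (322, highest other 1872) and 7 of 10 as many lists (5, highest other 11); a split with several times the real count points to structure among the embryos other than genotype. At E14.5, 2 of 10 gave as many genes (1708, highest other 1712) and 3 of 10 as many lists (12, highest other 15). With 10 splits a share under 0.05 cannot be reached. For the interaction, 29 of 100 relabellings gave as many genes (731, highest other 2870) and 68 of 100 as many lists (6, highest other 17), so regrouping of embryos is not excluded as their source. Over both ages 14 of 100 gave as many genes (1366, highest other 2870), while only 1 of 100, the real one, gave as many lists (18, highest other 17).

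More genes changed with age in HARE5Hs/Hs (6538) than in WT (5041), a difference of 1497 genes. In 35 of 100 relabellings of genotype within age the difference was as large (highest 3603), so regrouping of embryos is not excluded. Without E14.5 HARE5Hs/Hs replicate 3 the count was 5178 against 5204 in WT in the same fit. There WT kept all its embryos and HARE5Hs/Hs lost 1, which by itself can lower the HARE5Hs/Hs count. With 1 WT embryo left out in turn, the WT count was 3245 to 4843, below 5178. Leaving out other HARE5Hs/Hs libraries also moved the HARE5Hs/Hs count, from 4930 to 6443. The condition about other libraries was added to this test after those values were seen, and as first written it would have counted toward the single library. Neither regrouping nor the single library is excluded here.

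On the age axis E14.5 HARE5Hs/Hs embryos lay 0.191 later than WT (exact 2-sided p = 0.3). Without HARE5Hs/Hs replicate 3, which has hardly any Ttr (0.364 CPM) or Col1a1 (1.55 CPM), the difference was 0.104, between the bounds for and against a single embryo. The difference was lower still without WT replicate 3, the earliest E14.5 library (score 0.737), which this test did not cover. With gene-length offsets it was 0.192, but the offsets left 98.8% of the age calls in place in each genotype and do not measure RNA integrity, so this decides nothing and that explanation stays open. On the 117 cortical-list genes alone it was 0.194 (SE of the difference 0.0838, exact 2-sided p = 0.2); this passed the bound against a smaller share of neighbouring tissue, but by less than that SE, so the explanation stays open. Only a smaller share of neighbouring tissue was tested, yet such genes did not run 1 way at E14.5. The list mean was higher in HARE5Hs/Hs by 0.926 for ventral telencephalon and differed by −1.37 for meninges and mesenchyme. A single embryo, gene length or RNA integrity, less neighbouring tissue, genotype and the spread between embryos cannot be told apart.

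Erythroid genes stood higher in HARE5Hs/Hs at E14.5, with a median of 1.62. The share of measured members within 2 SE of that median was 1, so all moved by about the same factor, which fits red blood cells left in the tissue. Relabelling genotype within each age gave an exact 2-sided p of 0.015 for the list mean averaged over both ages, not for E14.5 alone (difference 1.09; 400 relabellings), but the list was picked from 30 after its values were seen, and adjusted over the 30 lists the value is 0.3. The smallest possible p is 0.005, so no single list could pass 0.05 after this adjustment by itself, and the adjusted value decides nothing. A difference between embryos that has nothing to do with genotype stays open.

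S phase genes differed in their age change between genotypes by a median of −0.25 (camera adjusted p = 3.42e-05; 0.945 with an estimated correlation). G2 and M phase genes differed by −0.32 (camera adjusted p = 8.7e-07; 0.945 with an estimated correlation). Diencephalon genes differed by 3.58 (camera adjusted p = 0.0301; 0.945 with an estimated correlation), a median set by members near 0 counts. Meninges and mesenchyme differed by −0.902 (camera adjusted p = 0.0301; 0.945 with an estimated correlation). Erythroid cells differed by 0.786 (camera adjusted p = 0.0034; 0.945 with an estimated correlation). Ribosomal proteins differed by −0.0956 (camera adjusted p = 0.000615; 0.945 with an estimated correlation).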

How the results depend on the processing

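limma voom, gene-length offsets and leaving E14.5 HARE5Hs/Hs replicate 3 out of contrasts that do not compare it were chosen only after the result was seen.

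Most calls of named genes with age held, list calls did not with an estimated correlation, and where a value moved the cause was not tested. Over all genes, 3203 of 5041 WT calls were kept without E14.5 WT replicate 1, and 4863 of 6538 HARE5Hs/Hs calls without E12.5 HARE5Hs/Hs replicate 2. Each named gene was compared in each setting. Named genes were picked for large folds or small p, and a gene called in neither fit also counts as the same. With age in WT, 887 of these comparisons with a library left out gave the same call, 58 a weaker, 6 a stronger and 1 a moved one. In HARE5Hs/Hs 794 gave the same, 26 a weaker, 1 a reversed and 1 a moved one, and other settings gave the same call 1199 and 1211 times. For lists, settings that keep all libraries gave 31 same and 23 weaker results at E14.5 and 32 same and 37 weaker over both ages. Among fits that leave out a library, the number of genes changed with age in WT ran from 3245 without E14.5 WT replicate 1 to 5204 without E14.5 HARE5Hs/Hs replicate 3, while limma voom gave 5761 and DESeq2 5432. For HARE5Hs/Hs against WT at E14.5 DESeq2 called 35 genes, and leaving out a library gave 0 to 19 (19 without E14.5 HARE5Hs/Hs replicate 1). For the genotype by age interaction DESeq2 called 1, and leaving out a library gave 0 to 2 (2 without E14.5 HARE5Hs/Hs replicate 1). Hspa1b, E14.5 against E12.5 in HARE5Hs/Hs, ran from −0.807 without E14.5 HARE5Hs/Hs replicate 3 to 4.99 without replicate 1. Fzd8 at E12.5 was −0.0181 by limma voom and ran from −0.177 without E12.5 HARE5Hs/Hs replicate 1 to 0.274 without E12.5 WT replicate 2. At E14.5 it ran from −0.0115 without E14.5 HARE5Hs/Hs replicate 1 to 0.0697 without E14.5 WT replicate 2. The Fzd8 interaction was 0.0461 by limma voom and ran from −0.254 without E12.5 WT replicate 2 to 0.198 without E12.5 HARE5Hs/Hs replicate 1, and over both ages Fzd8 ran from −0.0779 to 0.148 for the same 2 embryos in reverse order. The number of gene lists with an estimated correlation was 0 with age in WT, 0 with age in HARE5Hs/Hs, 0 at E12.5, 0 at E14.5, 0 for the interaction and 0 over both ages; by fry it was 0 at E12.5, 1 at E14.5, 0 for the interaction and 0 over both ages. Leaving out a library, the number of gene lists at E12.5 ran from 2 (without E12.5 WT replicate 3) to 10 (without E12.5 HARE5Hs/Hs replicate 2), for the interaction from 3 (without E12.5 WT replicate 3) to 13 (without E14.5 HARE5Hs/Hs replicate 1) and over both ages from 10 (without E12.5 WT replicate 3) to 18. With a library left out, camera adjusted p of the list neurons, HARE5Hs/Hs against WT at E12.5, ran from 6.73e-05 to 0.643. That of the list synapse and ion channels, HARE5Hs/Hs against WT at E12.5, ran from 1.21e-06 to 0.643; both were lowest without HARE5Hs/Hs replicate 2 and turned over without replicate 1. That of the list ribosomal proteins, HARE5Hs/Hs against WT at E12.5, ran from 5.51e-12 (without WT replicate 1) to 0.795 against 0.852 with all libraries, and its sign turned over without WT replicate 2 or HARE5Hs/Hs replicate 1. That of the list ribosomal proteins, genotype by age interaction, ran from 3.22e-08 to 0.798 and turned over without E12.5 WT replicate 1. That of the list cortical hem and choroid plexus, HARE5Hs/Hs against WT over both ages, ran from 0.00392 to 0.768 and turned over without E14.5 HARE5Hs/Hs replicate 3. With the replicate number as a block, 4714 genes changed with age in WT and 6248 in HARE5Hs/Hs, and 0 passed between genotypes.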

Other observations

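The exact list tests below were chosen only after the result was seen.

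Single genes of the forebrain patterning, hypoxia and p53 target lists changed with age in both genotypes, though the forebrain patterning list (camera adjusted p = 0.0904 and 0.176) and the p53 target list (camera adjusted p = 0.735 and 0.675) were not called. Fgf15, a growth factor gene, fell by 3.79 in WT (SE 0.55, edgeR adjusted p = 0.000466) and 3.68 in HARE5Hs/Hs (SE 0.54, edgeR adjusted p = 0.000266), and Sp8, a rostral transcription factor, by 1.03 (SE 0.16, edgeR adjusted p = 0.000741) and 1.82 (SE 0.17, edgeR adjusted p = 2.71e-05). Ndrg1, induced by low oxygen and by differentiation, rose by 3.63 (SE 0.31, edgeR adjusted p = 4.05e-05) and 4.10 (SE 0.31, edgeR adjusted p = 1.27e-05), while the glucose transporter gene Slc2a1 fell by 0.95 (SE 0.15, edgeR adjusted p = 0.000827) and 1.01 (SE 0.15, edgeR adjusted p = 0.000331). Of the p53 target genes, Trp53inp1 rose by 1.45 (SE 0.20, edgeR adjusted p = 0.000376) and 1.64 (SE 0.20, edgeR adjusted p = 0.00011) and Pmaip1, which promotes apoptosis, fell by 4.12 (SE 0.67, edgeR adjusted p = 0.000825) and 3.01 (SE 0.64, edgeR adjusted p = 0.00239).

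Ckap2 and Esco2, both of mitosis and chromatid cohesion, rose with age in WT by 0.26 (SE 0.09, edgeR adjusted p = 0.0368) and 0.34 (SE 0.12, edgeR adjusted p = 0.0421) and fell in HARE5Hs/Hs by 0.24 (SE 0.09, edgeR adjusted p = 0.0364) and 0.32 (SE 0.12, edgeR adjusted p = 0.0458); the phosphatase gene Ptprk ran the other way, falling by 0.30 (SE 0.10, edgeR adjusted p = 0.0366) and rising by 0.27 (SE 0.10, edgeR adjusted p = 0.0428). These 3 are the only genes called in opposite directions, they were named after their values were seen, and none passed for a genotype difference in its age change (−0.50, −0.66 and 0.57, edgeR adjusted p = 0.921 each).

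With genotype relabelled within each age (400 relabellings, smallest p 0.005), 4 of 30 lists had an unadjusted exact 2-sided p under 0.05: erythroid cells (0.015), Wnt pathway components (0.03), upper layer neurons (0.035) and immediate early genes (0.04), each 0.3 after adjustment over the lists. With that smallest p, no single list could pass 0.05 after adjustment by itself, so the adjusted values decide nothing. The Wnt pathway components list had a mean difference of −0.241 over the ages but was not called at E14.5 (camera adjusted p = 0.115; 0.584 with an estimated correlation). It includes Wnt8b of the cortical hem (37.5 ± 9.66 CPM in WT and 15.4 ± 15.7 CPM in HARE5Hs/Hs at E14.5), so the share of neighbouring tissue is not excluded as a source. The mean of neuron genes minus S, G2 and M phase genes stood 0.743 higher in HARE5Hs/Hs at E14.5 (SE 0.315, exact 2-sided p = 0.2). Counting neurons and cycling progenitors in sections from further litters, staged by more than the day, would show whether such a difference recurs between genotypes at a matched stage.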
